A study of Homo sapiens with 20 samples.

How the data were processed

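Gene expression was measured on 20 one-colour Agilent arrays of human RNA. 9 arrays carried RNA from blood spots dried on Guthrie cards, 9 carried RNA from matched buffy coats (the white cell layer of centrifuged blood), and 2 carried reference brain RNA, called brain a and brain b. Per the labels, blood spot RNA was extracted with a spin kit and 3 µg of cDNA was labelled with a genomic labelling system. Buffy coat and brain RNA was extracted with Trizol and 300 ng of total RNA was labelled with an amplification kit. By these labels the preparation differed between blood spots and the other groups throughout.

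The deposited scanner files, 1 per array, hold intensity values written by Agilent Feature Extraction 9.5.3.1 (named in the file headers and in the submitters' processing notes). The processed signal is background-subtracted and detrended within the array, with a surrogate value for spots not above background, and is not normalized between arrays. The same deposited files hold the mean spot intensity, the median local background intensity, and flags (unit: other) for spots well above background, saturated or non-uniform. The series' value table, deposited by the authors, holds log2 values with no description of their scale. Compared with the scanner values, they ranked like log2 of the mean minus the background signal (lowest rank correlation over the arrays 0.998). Their distributions were close but not identical within a sample type and differed between types, which was read as quantile normalization within each sample type and is not stated by the authors. Their medians were 5.26 in the blood spots, 5.74 in the buffy coats, 6.74 in brain a and 6.78 in brain b. They were used only as an alternative. Their centring between sample types is unknown.

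Flagged non-uniform spots were left out and spots of 1 probe were averaged, which gave 41000 probes. Of these, 23680 were named through a RefSeq accession in a table for assembly GRCh38, 2802 through a current symbol, and 1128 through an older symbol, and 13390 kept the file's name. Probe positions are those of the files, on build hg18, which is another build than the naming table's. Of 27526 named probes with a chromosome in the files, 101 lay on another chromosome than the naming table gives their gene, 5 of them in the gene lists, and no value of a gene named through such a probe is printed. 133 probes of Y-linked genes and of X inactivation transcripts were left out of every count and test, leaving 40867 probes and 30395 genes. Other X-linked genes were kept.

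The main values were log2 of the processed signal minus each array's 75th percentile. On the median array 47.97% of probes were well above background, so by the rule fixed before the data were examined the percentile was taken over the 3000 probes well above background on all 20 arrays. Each gene was represented by its probe with the highest mean over the 20 arrays. A gene was tested when that probe was well above background on a share of at least 0.5 of the arrays of at least 1 group. A difference in a gene well above background on only some arrays of the dimmer group rests partly on background-level values, so its size is uncertain. Each comparison was fitted on the arrays of its own groups with limma 3.58.1 (lmFit, then eBayes with a trend) in R 4.3.3, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. Where a gene was not well above background on any array of the dimmer group, the fold is given as "at least": the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal.

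21 gene lists were fixed before the data were examined: erythroid, platelet, neutrophil, monocyte, T cell, NK and cytotoxic, B cell, neuronal and synaptic, astrocyte, oligodendrocyte, cytosolic ribosomal protein, nuclear-encoded oxidative phosphorylation, proteasome, replication-dependent histone, immediate early and stress, interferon-stimulated, housekeeping, liver (an absent tissue), skin keratinocyte, endothelial and olfactory receptor. Lists with at least 5 measured genes were tested with limma's camera at its preset correlation, again with an estimated correlation, and with fry, which tests a list against no change instead of against the other genes, and adjusted over the lists of a comparison.

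Genes named in the text followed a rule fixed at the same time. In each comparison it took the 10 largest positive and the 10 largest negative log2 differences among called genes that were well above background on every array of the brighter group and on a share of at least 0.5 of the dimmer group's arrays, with no overlap between the groups' values, skipping unnamed transcripts. It added the 3 largest at-least folds in each direction, and up to 4 members of each list by size of the limma statistic. Fetal globin, HLA, KIR, immunoglobulin and T cell receptor, blood group and Y-linked genes and X inactivation transcripts were never named. All genes the rule took were carried through every alternative, and those printed for a list are its highest ranked members, with others of the 4 where they ran against their list or turned under an alternative. Some genes the rule took are not reported here, and those were also left out of the search for samples far from their group.

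Numbers of detected probes, spreads and donor correlations were compared with exact permutation tests. Files and labels gave 7 slides and 5 scan days. Slides 1 and 2 each held 4 blood spots, slide 3 held 1 blood spot and brain b, slide 4 held brain a, slide 5 held 1 buffy coat, and slides 6 and 7 each held 4 buffy coats. No slide held both blood spots and buffy coats. The alternatives covered normexp with an offset of 50, quantile normalization, median scaling, the percentile over all probes, the deposited value table, stricter and no filters, other uses of several probes, all arrays in 1 fit, array weights, no trend, slide blocks, the replicate block, and leaving out each array. Alternatives added after the data were seen left out the donor pair scanned on other days or the 2 dimmest blood spots, required every array of both groups above background, used 1 brain array for each blood group, used Spearman's rho for the donor correlation, and repeated the list tests with median scaling.

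The labels give a blood spot and a buffy coat of each donor the same number, so the donor pairs the samples. As a check, deviations from the group means correlated across genes with a median r of 0.0366 within the 9 pairs and exceeded 0.1 in 4 of them, beside a median of -0.00174 between pairs. Donors that shared a slide among blood spots also shared one among buffy coats. The check was not centred within slides, so it cannot tell donor from slide.

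The fits were tested on simulated data with the spread of each group as measured and 200 changed genes. These are far fewer than the calls in the data, so the shares recovered and false hold for this setting only. For blood spots against buffy coats (17239 genes) 10 of 100 genes changed 2-fold and 70 of 100 changed 4-fold were recovered, and 8 of 88 calls were false. For buffy coats against brain (22626 genes) 26 of 100 and 61 of 100 were recovered, and 2789 of 2881 calls were false. For blood spots against brain (21993 genes) 9 of 100 and 16 of 100 were recovered, and 796 of 821 calls were false. The brain arrays spread more than the blood groups, which a fit with a pooled spread does not allow for. Counts of calls against brain are therefore unreliable and may include many genes that differ only between the 2 brain arrays. The simulation drew the gap between those arrays as random, so it does not give the number of such genes. Array weights lowered the false calls to 155 and 154 but recovered 3 and 1 of the 100 genes changed 4-fold. The number of arrays limits the precision of every value. Figures were drawn with matplotlib 3.10.9, and files were read with Python 3.11.15 and pandas 2.3.3.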

Results

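RNA from 9 dried blood spots on Guthrie cards, 9 buffy coats of the same donors and a brain reference was measured on 20 arrays, 2 of them brain. The series asks whether archived cards hold usable expression data. Blood spots gave signal from fewer genes than buffy coats. Probes well above background numbered 12606 ± 5214 per array in blood spots and 22114 ± 3226 in buffy coats (mean ± SD, n = 9 each). The difference was -9508 probes (exact two-sided permutation test that ignored the donor pairing, p = 0.00037). Blood spots had fewer in 9 of 9 donor pairs. The counts ranged from 5297 to 22044 in blood spots and from 17749 to 28875 in buffy coats, and were 26297 in brain a and 23359 in brain b. As a share of probes, this was 30.9% ± 12.7 in blood spots, 54.2% ± 7.89 in buffy coats, and 64.6% and 57.2% in the brain arrays.

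**Figure D1:**
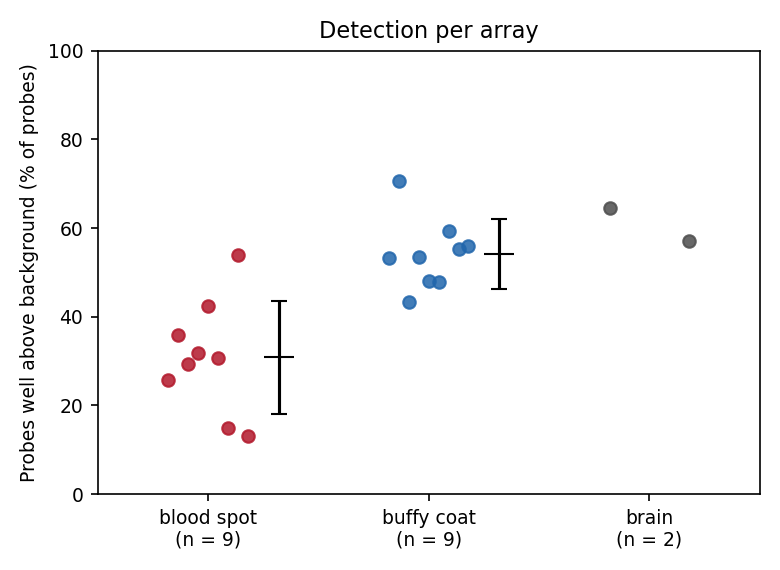
Percent of probes well above background on each array, by group; points are arrays and bars are the mean with 1 SD for the blood groups. Blood spots lie between 13.05% and 53.9% and buffy coats between 43.4% and 70.7%.

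At the level of genes, 8755 were well above background in blood spots and 16322 in buffy coats, and 7553 in both, where independent lists would share 4701. These 7553 genes made up 46.3% of the buffy coat genes and 86.3% of the blood spot genes. Marker genes of blood cells were unevenly detected in blood spots. Of the 32 erythroid genes on the array, 26 were well above background in blood spots and 26 in buffy coats. Of the 25 neutrophil genes, 18 and 22 were, of the 23 T cell genes 14 and 23, of the 20 NK and cytotoxic genes 12 and 20, and of the 20 B cell genes 6 and 20. Cytosolic ribosomal protein genes were detected almost completely in both, 83 and 84 of 86. Olfactory receptor genes, which blood cells hardly express, were detected for 3 and 8 of 114, and liver genes for 0 and 1 of 22.

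Blood spots against buffy coats asked how the profile from a card differs from that of the buffy coat of the same donor. By limma's camera at its preset correlation, genes of red cells were higher in blood spots, and genes of T cells, NK cells, monocytes, platelets, ribosomes, mitochondrial respiration and the proteasome were lower. None of these 8 lists passed with an estimated correlation, and the platelet, monocyte and NK lists did not pass with quantile normalization. SLC25A37, the iron importer of red cell mitochondria, was higher by 6.50 (log2, SE 0.29, adjusted p = 3.14e-17), and HEMGN, a red cell nuclear protein, by 6.78 (SE 0.36, well above background in 7 of 9 buffy coats). PF4, a platelet chemokine, fell by 4.92 on the log2 scale (SE 0.33), and RPS19, a ribosomal protein, fell by 5.50 (SE 0.26). CD6, a T cell surface protein, fell by 7.17 (SE 0.37). It was well above background in 1 of 9 blood spots, so the size of its fall rests on background-level values. All of these were fitted on 9 arrays per group.

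Of 17524 genes tested, 12680 were called, 6913 higher and 5767 lower in blood spots, and 12108 of them by at least 2-fold. Groups did not overlap for 6553 genes (37.4%, where chance gives 0.00411%), and all 6553 were called. The share of calls that were higher depended on the scaling. It was 54.5% in the main fit, 75.7% with normexp, 34.0% with quantile normalization, 26.1% with median scaling, 41.5% with the percentile over all probes and 16.3% in the deposited table. The median difference of all tested genes was 0.28 in the main fit and 1.16, -1.01, -1.40, -0.40 and -2.17 in those settings, in that order, so list shifts are given relative to the median of all genes. These shifts depended on the scaling too.

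TENT5C, a poly(A) polymerase, had the largest rise among genes measured in both groups, 12.80 (log2, SE 0.41, adjusted p = 3.52e-20, probe A_24_P935893, chromosome 1 from 117970904 to 117970963). It was followed by AD7C-NTP at 12.68, the cyclophilin PPID at 11.69, the RNA polymerase subunit POLR2J2 at 11, the transcription factor PAX4 at 10.83, ACBD7 at 10.73, ASB16 at 10.51, PSPH, of serine synthesis, at 10.32, the mucin MUC3A at 10.17 and the fatty acid transporter SLC27A1 at 9.95. The largest fall was that of IFITM5, a bone cell protein, at -8.34 (SE 0.39, adjusted p = 1.22e-16, chromosome 11 from 289345 to 289404). CDC42EP5 (-8.07), the tryptase TPSG1 (-7.97), PARP10 (-7.92), the urotensin receptor UTS2R (-7.64), the muscle cytochrome oxidase subunit COX6A2 (-7.62), the transcription factor SOX3 (-7.61), MEX3D (-7.61), PRR5 (-7.29) and the orphan receptor GPR153 (-7.21) followed. In the dimmer group the probes of TENT5C, IFITM5 and MEX3D were well above background on 5 of 9 arrays, those of UTS2R and SOX3 on 6, those of AD7C-NTP, MUC3A and PARP10 on 7, those of PPID, PAX4, CDC42EP5, TPSG1, COX6A2, PRR5 and GPR153 on 8, and the others on 9. SOX3 was 0.14 when all its probes were averaged. Whether the signal of these probes comes from the RNA of the named genes was not tested. For PPID, PSPH, SLC27A1, PARP10 and MEX3D another probe of the gene was called in the opposite direction, as for 782 of the 3294 called genes with several probes. PRO0471, HSA251708 and the cohesin protector SGO1 were not well above background in any buffy coat and were at least 479-fold, 240-fold and 173-fold higher in blood spots. The calcium channel CACNA1E, FBXW5 and the kinase CSNK1G2 were not well above background in any blood spot and were at least 35.4-fold, 26.1-fold and 20.8-fold lower.

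Among blood cell lists, erythroid genes lay 3.01 above the median of all genes (camera adjusted p = 0.000101, and adjusted p = 0.358 with an estimated correlation), with 24 of 29 higher and 2 lower over all genes and 27 called when adjusted over the list alone. T cell genes lay at -2.76, with 18 of 23 lower and 4 higher over all genes and 23 called adjusted over the list alone (adjusted p = 0.00046, and 0.132 with an estimated correlation). LCK, the kinase of the T cell receptor, followed CD6 at -5.75 (4 of 9 blood spots well above background). NK and cytotoxic genes lay at -2.55, with 16 of 20 lower and 2 higher and 18 called adjusted over the list alone (adjusted p = 0.00142, and 0.358 with an estimated correlation). Their highest ranked members were KLRB1, an NK cell receptor, at -5.30 (4 of 9 blood spots well above background) and the granule protease GZMA at -3.62. Monocyte genes lay at -2.03, with 11 of 19 lower and 5 higher and 16 called adjusted over the list alone (adjusted p = 0.0384, and 0.358 with an estimated correlation). CLEC7A, a receptor for fungal glucans, was higher at 7.52 (4 of 9 buffy coats well above background), and FCN1, a monocyte lectin, was lower at -4.27. Platelet genes lay at -1.19, with 9 of 19 lower and 3 higher and 11 called adjusted over the list alone (adjusted p = 0.0472, and 0.644 with an estimated correlation). With quantile normalization the platelet, monocyte and NK lists did not pass (adjusted p = 0.386, 0.419 and 0.0662). The erythroid shift was 3.89 with quantile normalization and 1.78 with normexp, the monocyte shift -0.95 and -2.44, the NK and cytotoxic shift -1.76 and -2.16, the T cell shift -2.15 and -2.63, and the platelet shift -0.91 and -1.66.

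Cytosolic ribosomal protein genes lay at -2.60 relative to the median of all genes, with 75 of 84 lower and 2 higher over all genes and 81 called adjusted over the list alone (adjusted p = 1.18e-18, and 0.132 with an estimated correlation). RPS19 and RPL10L fell by 5.50 and 5.75, and RPS12 was higher at 3.79. Nuclear-encoded oxidative phosphorylation genes lay at -2.43, with 66 of 81 lower and 3 higher and 69 called adjusted over the list alone (adjusted p = 2.15e-12, and 0.0642 with an estimated correlation). COX6A1 in that list was -3.78, but 0.12 when its probes were averaged. Proteasome genes lay at -2.01, with 25 of 37 lower and 2 higher and 27 called adjusted over the list alone (adjusted p = 7.59e-06, and 0.0642 with an estimated correlation), and the subunit PSMB4 fell by 3.57. With quantile normalization and normexp the ribosomal shift was -0.80 and -3.37, that of oxidative phosphorylation -1.58 and -2.69, and that of the proteasome -0.95 and -2.12. No list passed with the estimated correlation in limma's camera, and 4 of 20 had an unadjusted p under 0.05, while fry, which tests each list against no change and not against the other genes, called 18.

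The other 12 lists did not pass in the main fit. Neutrophil genes had a median of 1.63, which turned negative with median scaling and in the deposited table as the median of all genes fell. Relative to that median they lay at 1.35 in the main fit and with median scaling, 1.98 with quantile normalization, 0.41 with normexp and 0.70 in the deposited table, with 14 of 23 higher and 2 lower and 16 called adjusted over the list alone (adjusted p = 0.0698, and 0.00421 with quantile normalization, where the list passed). FPR2 and CXCR1, chemoattractant receptors of neutrophils, were 4.32 and 5.17 higher. B cell genes had 6 of 20 higher and 9 lower (15 adjusted over the list alone, adjusted p = 0.228), with CD79A of the B cell receptor at -4.29. Housekeeping genes had 6 of 20 higher and 10 lower (16 adjusted over the list alone, adjusted p = 0.0698, and 0.00636 with normexp), with RPLP0 at -5.47. IPO8 was at 6.94, a size that rests on background-level values (1 of 9 buffy coats well above background). Replication-dependent histone genes had 18 of 59 higher and 28 lower (46 adjusted over the list alone, adjusted p = 0.0547, and 0.00679 with normexp), with H4C3 at -4.56. Immediate early and stress genes had 12 of 30 higher and 10 lower (22 adjusted over the list alone, adjusted p = 0.79). Interferon-stimulated genes had 11 of 28 higher and 8 lower (19 adjusted over the list alone, adjusted p = 0.877), with TRIM22 at 3.43. ISG15 was at -6.71, a size that rests on background-level values (1 of 9 blood spots well above background). Neuronal and synaptic genes had 4 of 10 higher and 3 lower (7 adjusted over the list alone, adjusted p = 0.877), astrocyte genes 1 of 5 and 1 (2, 0.948), and oligodendrocyte genes 2 of 6 and 2 (4, 0.686). Skin keratinocyte genes had 5 of 9 higher and 3 lower (8, 0.715), endothelial genes 2 of 7 and 4 (6, 0.715), and olfactory receptor genes 5 of 8 and 1 (6, 0.228). Liver genes were too few to test.

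Buffy coats against brain compared white cells with a reference tissue under 1 labelling kit, per the labels. Genes of platelets, T cells, NK cells, monocytes, neutrophils and B cells were higher in buffy coats, and genes of neurons, astrocytes and oligodendrocytes were lower. With an estimated correlation the platelet and oligodendrocyte lists did not pass (adjusted p = 0.0569 and 0.0961). PF4 was higher by 11.68 (log2, SE 0.55, adjusted p = 7.76e-09), FCN1 by 10.75 (SE 0.39) and CD52, a lymphocyte surface protein, by 10.38 (SE 0.62). GFAP, the astrocyte filament protein, was lower at -11.50 (SE 0.66, adjusted p = 2.35e-08, chromosome 17 from 40338530 to 40338589) and NEFM, a neurofilament protein, at -11.41 (SE 0.60). These values rest on 9 buffy coats and 2 brain arrays of a reference RNA, whose spread may be technical only. PF4, FCN1 and CD52 were well above background on 1 of the 2 brain arrays, GFAP in 8 of 9 buffy coats and NEFM in 6.

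Of 22876 genes, 15162 were called, 3002 higher and 12160 lower in buffy coats. The groups did not overlap for 11958 genes (52.3%, where chance gives 3.64% if the spreads are equal), of which 11675 were called. The spreads were not equal, and on simulated data with the measured spreads 2622 of 2789 false calls had no overlap either. The share of calls higher in buffy coats was 19.8% in the main fit, 24.5% with normexp (6227 calls), 51.1% with quantile normalization, 66.6% with median scaling, 53.1% with the percentile over all probes and 36.6% in the deposited table. The median of all genes was -1.65 in the main fit and -1.19, -0.09, 0.48, -0.16 and -0.68 in those settings. With array weights 2328 genes were called. On simulated data with 200 changed genes, 2789 of 2881 calls of the main fit were false. That share depends on the number of changed genes and is not that of the 15162 calls.

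CD2, GZMA, the lectin LGALS2, FGFBP2, the signalling regulator RGS18, the granule protease GZMB and the T cell adaptor SKAP1 were 9.70, 9.44, 9.17, 9.07, 9, 8.99 and 8.94 higher in buffy coats. GPRC5B (-11.10), DKK3 (-10.50), AIF1L (-10.36), the glutamate transporter SLC1A3 (-10.22), TTYH1 (-9.81), the kinesin KIF5C (-9.70), SCHIP1 (-9.61) and RCAN2 (-9.52) were lower. The higher genes were well above background on 1 brain array, and the lower ones in 5 to 8 of 9 buffy coats. PPBP, a platelet chemokine, CCR7, a lymphocyte homing receptor, and MPIG6B, a platelet receptor, were not well above background on either brain array and were at least 1088-fold, 606-fold and 566-fold higher in buffy coats. FAM107A, TMEM130 and PCP4 were not well above background in any buffy coat and were at least 2639-fold, 2310-fold and 2089-fold lower.

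Relative to the median of all genes, T cell genes lay 8.31 higher in buffy coats, with 22 of 23 higher and 1 lower over all genes and 23 called adjusted over the list alone (adjusted p = 3.08e-27). NK and cytotoxic genes lay at 8.87 (19 of 20 higher, 19 adjusted over the list alone), monocyte genes at 6.31 (17 of 18 higher, 17), neutrophil genes at 5.42 (21 of 22 higher, 21) and B cell genes at 5.2 (16 of 20 higher, 16). Neuronal and synaptic genes lay at -5.89 (24 of 26 lower, 24 adjusted over the list alone) and astrocyte genes at -8.05 (15 of 15 lower, 15). These 7 lists also passed with an estimated correlation (adjusted p between 0.000793 and 0.0489). Platelet genes lay at 6.34 (16 of 19 higher, 17 adjusted over the list alone, adjusted p = 0.0569 with an estimated correlation) and oligodendrocyte genes at -6.10 (17 of 19 lower, 17, adjusted p = 0.0961 with an estimated correlation). LCK was at least 246-fold higher in buffy coats and KLRB1 at least 198-fold.

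Cytosolic ribosomal protein genes lay at 3.30 (67 of 84 higher, 69 adjusted over the list alone, adjusted p = 0.164 with an estimated correlation), with RPS15A at 2.82. RPL15 was 2.66, but -0.11 when its probes were averaged. Histone genes lay at 2.86 (30 of 59 higher and 4 lower, 34 adjusted over the list alone, adjusted p = 0.0696 with an estimated correlation). Interferon-stimulated genes lay at 2.45 (12 of 28 higher and 4 lower, 16, adjusted p = 0.183 with an estimated correlation), with MX2 at 4.75 (1 brain array well above background) and IFI27 at -5.46. Immediate early and stress genes lay at 1.93 (11 of 30 higher and 10 lower, 21, adjusted p = 0.537 with an estimated correlation), with a median of 0.28 that turned negative with normexp (0.81 relative to all genes there) and a mean of -0.32. Erythroid genes lay at 1.81 (7 of 27 higher and 8 lower, 14, adjusted p = 0.556 with an estimated correlation), with a median of 0.16 that turned negative with normexp (0.85 relative to all genes there). The erythroid list did not pass with quantile normalization or normexp (adjusted p = 0.141 and 0.425), immediate early and stress genes did not with quantile normalization (0.0608), and endothelial genes did with it (0.0158). Not called were oxidative phosphorylation (1 of 84 higher and 40 lower, 35 adjusted over the list alone, adjusted p = 0.911), proteasome (5 of 37 and 15, 19, 0.195), housekeeping (3 of 20 and 10, 14, 0.392), liver (0 of 6 and 5, 5, 0.1), skin keratinocyte (2 of 12 and 4, 6, 0.386), endothelial (0 of 15 and 9, 9, 0.0536) and olfactory receptor genes (3 of 13 and 7, 11, 0.911). PSMD1 of the proteasome was -1.98, but 0.15 with median scaling, where the median of all genes moved alike, from -1.65 to 0.48. TTR, a transport protein of the liver list that the choroid plexus also makes, was at least 2011-fold lower in buffy coats.

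Blood spots against brain differed in both tissue and, per the labels, preparation. Genes of neutrophils, NK cells, T cells, red cells, platelets, monocytes and B cells were higher in blood spots, and genes of astrocytes and mitochondrial respiration were lower. CD2, a T cell adhesion protein, was higher by 8.76 (log2, SE 0.69, adjusted p = 3.88e-09, chromosome 1 from 117113301 to 117113360) and ALAS2, the red cell enzyme of haem synthesis, by 8.52 (SE 0.88). NDRG4, a brain protein, was lower at -8.46 (SE 0.99, adjusted p = 1.04e-06) and the sodium pump subunit ATP1B1 at -8.31 (SE 0.96). These values rest on 9 blood spots and 2 brain arrays of a reference RNA, whose spread may be technical only. CD2 and ALAS2 were well above background on 1 brain array, NDRG4 in 6 of 9 blood spots and ATP1B1 in 5.

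Of 22243 genes, 5706 were called, 2153 higher and 3553 lower in blood spots, all by at least 2-fold. The groups did not overlap for 5688 genes (25.6%, where chance gives 3.64% if the spreads are equal), of which 4424 were called. On simulated data with the measured spreads 785 of 796 false calls had no overlap either. The share of calls higher in blood spots was 37.7% in the main fit, 46.4% with normexp, 42.5% with quantile normalization, 46.9% with median scaling, 63.6% with the percentile over all probes and 5% in the deposited table (13059 calls). The median of all genes was -0.50 in the main fit and 0.25, -0.44, -0.05, 0.31 and -2.10 in those settings. Slide 3 held 1 blood spot and brain b. With slide as a fixed block, where the estimate rests on that slide alone, 3477 genes were called. With array weights 875 genes were called. On simulated data with 200 changed genes, 796 of 821 calls of the main fit were false. That share depends on the number of changed genes and is not that of the 5706 calls.

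The T-bet transcription factor TBX21 was 8.35 higher in blood spots, MUC3A 8.23, the myeloid nuclear protein MNDA 8.14, GBP5 8.06, ST8SIA4 7.88, PRO0471 7.86 and the erythroid transcription factor NFE2 7.86. NDRG2 (-7.50), NEFM (-7.35), the prostaglandin synthase PTGDS (-7.28), the myelin enzyme CNP (-7.11), BEX2 (-6.82), TCEAL5 (-6.71), the glutamate receptor subunit GRIN2C (-6.70) and DKK3 (-6.56) were lower. Of the higher genes MUC3A and MNDA were well above background on both brain arrays and the others on 1, and the lower genes in 5 to 8 of 9 blood spots. TENT5C, the lysozyme LYZ and the red cell carbonic anhydrase CA1 were not well above background on either brain array and were at least 2303-fold, 595-fold and 194-fold higher. GFAP, the chaperone CRYAB and FAM107A were not well above background in any blood spot and were at least 565-fold, 389-fold and 202-fold lower.

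Relative to the median of all genes, neutrophil genes lay 6.40 higher in blood spots (18 of 20 higher over all genes, 18 adjusted over the list alone, 6.06 before that subtraction within slide 3). NK and cytotoxic genes lay at 6.32 (11 of 12 higher, 11, 5.23 within the slide), erythroid genes at 4.72 (17 of 29 higher and 2 lower, 19, 3.65 within the slide), T cell genes at 4.70 (13 of 18 higher, 15, 4.45 within the slide) and platelet genes at 4.57 (11 of 15 higher and 3 lower, 14, 4.34 within the slide). Monocyte genes lay at 3.28 (9 of 18 higher, 11, 2.80 within the slide) and B cell genes at 2.88 (4 of 11 higher, 4, 3.78 within the slide). Astrocyte genes lay at -6.17 (14 of 15 lower, 15, -8.88 within the slide) and oxidative phosphorylation genes at -2.42 (61 of 84 lower, 72, -1.79 within the slide). Interferon-stimulated genes lay at 1.78 (8 of 27 higher and 2 lower, 10, 1.20 within the slide), with a median that turned negative in the deposited table (1.40 relative to all genes there). These 10 lists also passed with an estimated correlation (adjusted p between 0.000532 and 0.0499). HBD, a haemoglobin chain of adult red cells, was 7.51 higher in blood spots, and HEMGN at least 116-fold.

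Neuronal and synaptic genes lay at -4.28 (19 of 26 lower, 23 adjusted over the list alone, adjusted p = 0.0506 with an estimated correlation, -7.25 within the slide). Oligodendrocyte genes lay at -4.61 (15 of 19 lower and 1 higher, 17, adjusted p = 0.168 with an estimated correlation, -5.75 within the slide) and proteasome genes at -1.55 (16 of 37 lower and 1 higher, 21, adjusted p = 0.0523 with an estimated correlation, -1.20 within the slide). Histone genes lay at 1.33 (5 of 55 higher and 3 lower, 1, adjusted p = 0.337 with an estimated correlation, 1.25 within the slide), immediate early and stress genes at 0.86 (10 of 30 and 4, 16, adjusted p = 0.369 with an estimated correlation, 0.01 within the slide beside 0.36 over all arrays) and olfactory receptor genes at 1.98 (2 of 12 and 0, 2, adjusted p = 0.256 with an estimated correlation, -0.61 within the slide), and the medians of these 3 lists turned negative in the deposited table (1.04, 0.79 and 1.73 relative to all genes there). Not called were ribosomal (1 of 84 higher and 5 lower, 2 adjusted over the list alone, adjusted p = 0.338), housekeeping (1 of 20 and 8, 11, 0.0656), skin keratinocyte (1 of 10 and 1, 3, 0.119) and endothelial genes (1 of 15 and 3, 5, 0.257). With normexp the ribosomal and housekeeping lists passed as lower (adjusted p = 0.00803 and 0.00622) and immediate early and stress genes did not pass (0.0805), and with quantile normalization olfactory receptor genes did not (0.0561). RPLP0 was -2.34, but 0.89 with slide as a fixed block. MCL1 was 1.85, but -0.34 in the deposited table, where the median of all genes moved from -0.50 to -2.10.

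**Figure D2:**
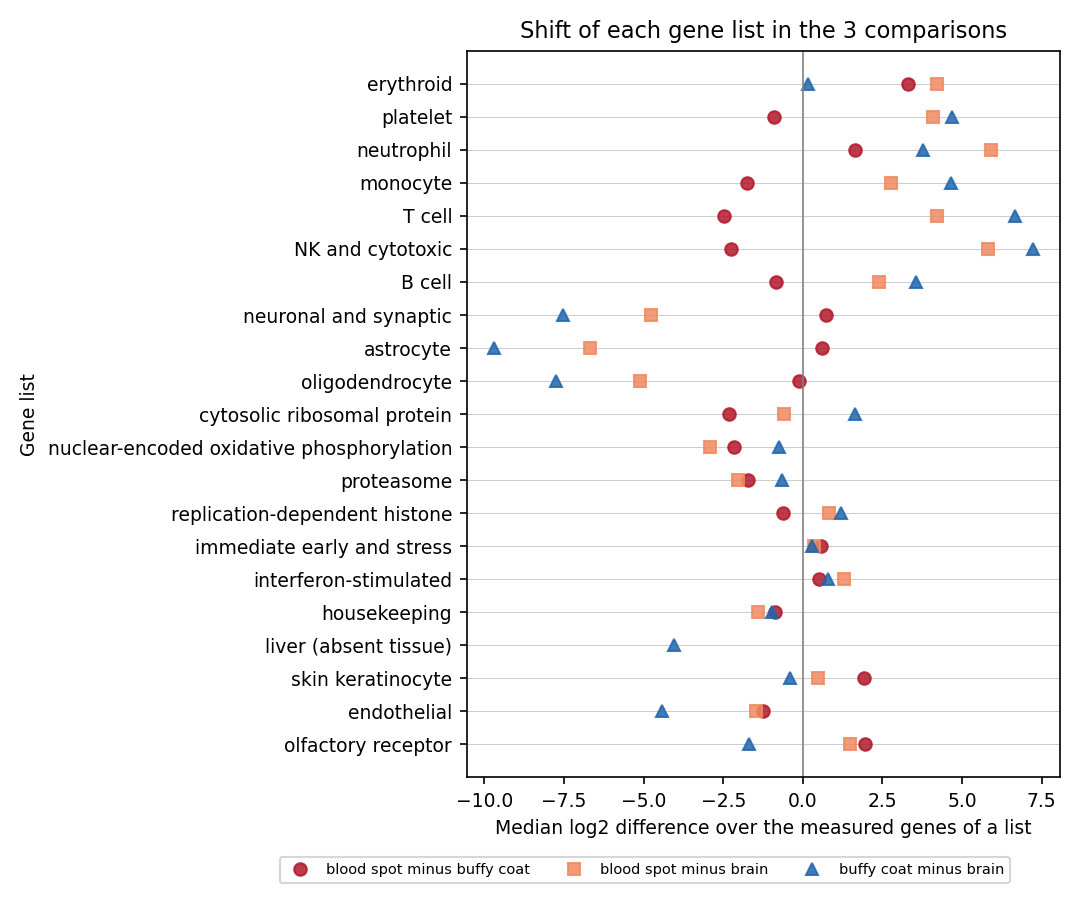
Median log2 difference over the measured genes of each list, in the 3 comparisons; each point is 1 list in 1 comparison and values are not relative to the median of all genes. Erythroid genes are at 3.29 between blood spots and buffy coats and at 0.16 between buffy coats and brain, the latter negative with normexp.

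Across the 7553 genes well above background in both blood groups, the group means of blood spots and buffy coats correlated at r = 0.37 (Spearman's rho 0.33). Blood spots and brain correlated at 0.47 and buffy coats and brain at 0.62, over the 8349 and 15283 genes above background in both groups. These sets of genes differ, so the 3 values do not rank the groups. Over all 30395 genes blood spots correlated at 0.63 with buffy coats and 0.60 with brain, and buffy coats with brain at 0.71. Genes are not independent replicates, so no p is given. The brain arrays differed in this respect. Blood spots correlated at 0.27 with brain a and 0.59 with brain b, and buffy coats at 0.73 with brain a and 0.34 with brain b. Between arrays of 1 group, the median r was 0.83 for blood spots (0.74 to 0.86), 0.97 for buffy coats (0.93 to 0.98) and 0.52 for the pair of brain arrays.

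**Figure D3:**
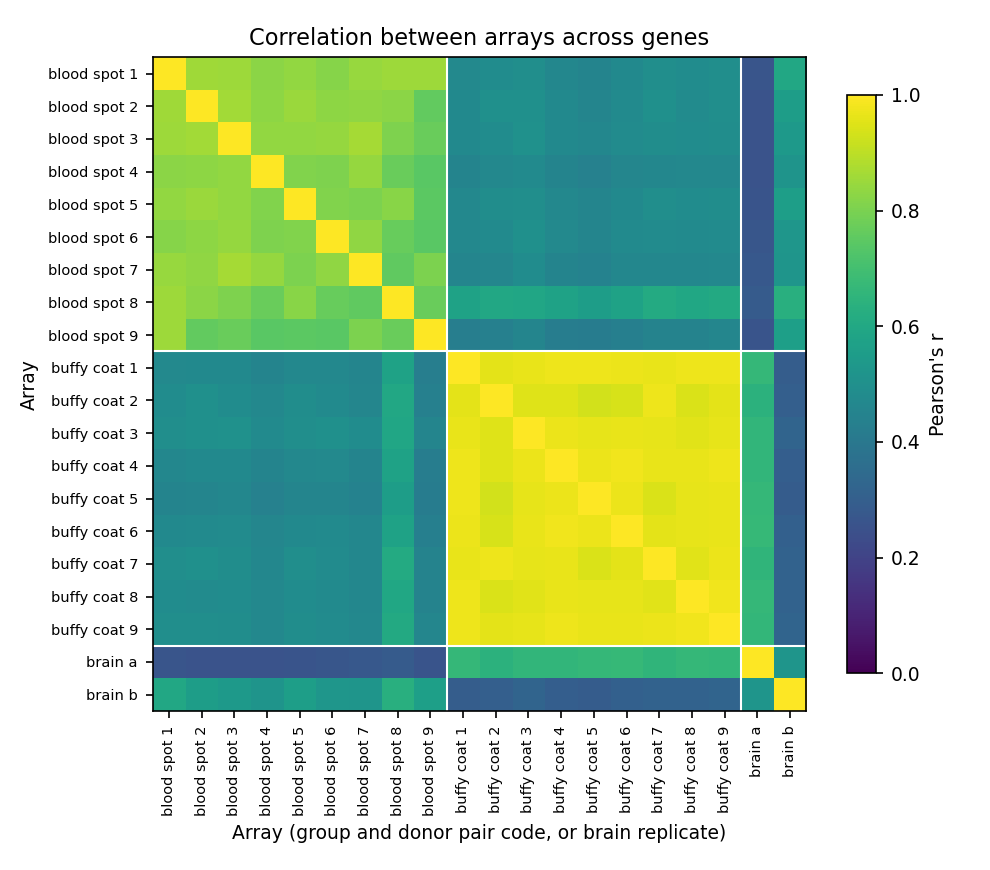
Pearson's r across genes for each pair of the 20 arrays, with white lines between groups and arrays named by group and donor pair code or brain replicate. Buffy coats correlate with each other at 0.93 to 0.98 and blood spots at 0.74 to 0.86, and the 2 brain arrays at 0.52.

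Values of single genes spread more between blood spots than between buffy coats. The median SD over 7466 genes was 0.88 in blood spots and 0.47 in buffy coats. The median difference was 0.36, and 0.20 over the genes above background on all 20 arrays. Of the 7466 genes, 82.1% spread more in blood spots. Exact permutation within the 9 pairs gave a two-sided p = 0.0039, the smallest that the 512 exchanges can give. The exchanged values were not centred on their group means, so the difference between the groups entered both spreads after an exchange. This p therefore does not test whether the spreads are equal. Across the 9 donors, blood spot and buffy coat values of a gene correlated weakly. The mean over genes was r = 0.0884 (exact two-sided permutation p = 0.0175 over 362880 pairings) and rho = 0.0880 (exact permutation p = 0.0184), and 59.1% of genes had an r above 0. Centred within slides, the mean r was 0.0749 and did not pass (permutation p = 0.0521). Centring set the donor alone on its slide to 0, and the pairings crossed slides. That p is therefore not an exact test of donors within slides. The r and rho are 2 forms of 1 relation, and no other relation across donors was computed except the alternatives.

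The differences of both blood groups from brain correlated across 23051 genes at r = 0.40, with a covariance of 2.89. Both use the same brain arrays, and unchanged groups simulated against those arrays gave r = 0.95 and a covariance of 2.18, a difference in covariance of 0.71. Over the 7322 genes above background in all 3 groups the covariance was 1.03 and the simulated one 2.10. The simulation took the gap between brain a and brain b as random. Across genes that gap followed the difference of blood spots from buffy coats (r = 0.80). The simulated values are therefore no measure of chance here, and neither difference in covariance measures shared signal. With no shared array, the difference of blood spots from brain b and of buffy coats from brain a correlated at r = 0.62, and the opposite assignment of the brain arrays gave -0.20.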

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

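The tests of labelling, of the shared slide and of whole blood RNA in brain b were chosen after the result was seen. In 362 groups of 9 values, made of detection, array correlation and the genes taken by the naming rule in each blood group, 14 held 1 sample whose gap to the nearest other, as a share of the group's range, was above Dixon's limit. That is 3.87%, where chance flags about 1 in 20. Among genes in blood spots, the shares were 0.674 for MS4A1 (CD20 of B cells), 0.632 for TCEAL5, 0.592 for MAG, 0.58 for HSA251708, 0.56 for PSMB10, 0.554 for ATP1B1, 0.525 for TTR and 0.515 for CSF1R. In buffy coats they were 0.603 for EGR1, 0.603 for KRT1, 0.54 for HSA251708, 0.528 for MX2 and 0.515 for SAMD9L. The median correlation of a buffy coat with the other arrays of its group gave 0.613.

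The arrays' spike-in controls, which the comparisons did not use, also gave a signal. Their median processed signal was 4400 in buffy coats, 3700 in brain a, 71.8 in brain b and 8.41 in blood spots. The share of the 320 spike-in spots well above background had a median of 80.6% in buffy coats and 20.3% in blood spots, and was 80% in brain a and 50.3% in brain b.

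Brain a and brain b differed in genes and in spike-in signal although the labels give them 1 preparation. Brain b correlated across genes with the 8 blood spots of other slides at a median of 0.5496 (0.5195 to 0.6003) and with brain a at 0.523. Preparation of brain b as for the blood spots is therefore a candidate explanation, though that range holds the value with brain a. The median spike-in signal of brain b (71.8) lay between that of blood spots (8.41) and of brain a (3700). The slide that brain b shared with 1 blood spot is argued against, since its correlation with blood spots of other slides lay 0.2897 above that of brain a. Whole blood RNA in brain b would raise erythroid genes. Their median in brain b minus brain a was -1.70, beside -0.13 for all genes, which goes against it. That median lay at percentile 0.32 of random lists of the same size. Random lists take genes as independent, so the percentile alone decides nothing. RNA of some white cells or platelets stays open, since T cell (1.23), NK and cytotoxic (1.24), platelet (0.94), neutrophil (0.63) and B cell genes (0.44) lay higher in brain b. Well above background on a brain array were 11 of 23 T cell, 8 of 20 NK and cytotoxic, 9 of 19 platelet and 9 of 20 B cell genes. The medians of these 4 lists therefore rest largely on background-level values. For neutrophil genes it was 15 of 25. Monocyte genes (-0.67) lay lower, and brain b correlated less with buffy coats (median 0.305) than brain a did (0.661). The labels give brain b the buffy coat protocol, the scanner files do not record the labelling, and no biological explanation was tested.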

How the results depend on the processing

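Alternatives that left out a donor pair or the 2 dimmest blood spots, asked for every array of both groups, used 1 brain array per blood group, took Spearman's rho or repeated the list tests with median scaling were chosen after the data were seen. The cause was not tested for any change below unless the setting's own construction gives it. For blood spots against buffy coats, scalings, slide and array weight settings kept the count of 12680 within 1.5 times, but not all of the genes. Of the 12680, 8263 were called in the same direction and 2231 in the opposite one in the deposited table, 10053 and 267 with quantile normalization, 9262 and 92 with median scaling, 10247 and 52 with normexp, and 11417 and 343 with the mean of all probes. The replicate block called 12866 genes, 12581 of the 12680 among them, and called S100B, which the main fit did not (1.55 with the block, adjusted p = 0.00642). It changed no other call of a list or of a gene taken by the naming rule. Filters changed the number of genes tested: without a filter 25714 genes were called, with both groups above background 6050, and with every array of both 2265. For buffy coats against brain, normexp gave 6227 calls, both groups above background 8277, and array weights 2328, beside 15162. For blood spots against brain, the deposited table gave 13059 calls, both groups above background 2671, all 20 arrays in 1 fit 8561, array weights 875 and the fixed slide block 3477, beside 5706. Leaving out 1 array gave 12515 to 13040 calls for blood spots against buffy coats, 12499 to 15993 for buffy coats against brain and 2230 (without brain a) to 7381 (without brain b) for blood spots against brain. The fits without a brain array take its spread from the other group. A fixed slide block and leaving out shared slides gave no value for the comparisons with buffy coats, since no slide held buffy coats with another group.

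Detection and spread differences kept their direction and side of the threshold, though the exchanges used for the spread do not test equal spread. The donor correlation was 0.0749 when centred within slide and group (permutation p = 0.0521), no longer past the threshold. The pairings behind that p crossed slides, so it is not an exact test within slides. The overlap of detected genes was 2613 with every array of a group and 11763 over the 99th percentile of negative controls. Group means of blood spots and buffy coats correlated at 0.628 over all genes. Over genes above background on all 20 arrays, blood spots correlated with each other at 0.875 and the brain arrays at 0.469. The blood-minus-brain correlation of 0.404 was 0.190 over genes above background in all groups, 0.616 with brain b for blood spots and brain a for buffy coats, and reversed at -0.196 with the opposite assignment. With an estimated correlation camera called 0 of 20 lists for blood spots against buffy coats (fry, against no change, 18, and 4 at an unadjusted p under 0.05), 7 of 21 for buffy coats against brain and 10 of 20 for blood spots against brain. With median scaling camera called 6 lists for blood spots against buffy coats (8 in the main fit, platelet and monocyte lost), 17 for buffy coats against brain (14, with 1 lost and 4 gained) and 15 for blood spots against brain (16). No called list passed in the opposite direction under an alternative, but 2 called lists of buffy coats against brain (erythroid, and immediate early and stress) turned direction with fry without passing. Relative to the median of all genes, the shift changed sign with normexp, quantile normalization or the deposited table in 5 lists for blood spots against buffy coats, 3 for buffy coats against brain and 1 for blood spots against brain, and in 0 called lists.

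Of the values of named genes under alternatives, 8 of 3646 reversed for blood spots against buffy coats, 2 of 2390 for buffy coats against brain and 2 of 2637 for blood spots against brain, and 18, 71 and 132 no longer passed the threshold. These values are not relative to the median of all genes, which the scalings moved, so the counts include turns shared with all genes. Most of these fell on few settings: for blood spots against brain 31 genes of 100 were lost or reversed with the fixed slide block, 28 with array weights and 20 without brain a, and for buffy coats against brain 33 of 102 with array weights, 15 with normexp and 13 with median scaling. With the mean of all probes the reversed ones were RPL15 in buffy coats against brain (-0.11) and COX6A1 (0.12), SOX3 (0.14) and VWF (0.10) in blood spots against buffy coats. In the deposited table they were MCL1 in blood spots against brain (-0.34) and MAG (-0.19), MBP (-0.86), OR11A1 (-0.61), OR4D2 (-0.40) and SLC1A3 (-0.99) in blood spots against buffy coats. Each of these lay above the median of all genes in that setting, which was -2.10 against brain and -2.17 against buffy coats. PSMD1 was 0.15 with median scaling in buffy coats against brain, where the median of all genes was 0.48. RPLP0 was 0.89 with the fixed slide block in blood spots against brain. Signal over background limits the blood spot values, with a mean of 12606 of 40867 probes well above it per array, beside 22114 in buffy coats.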

Other observations

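The test of the labelling protocol over all genes was chosen after the result was seen, so was the assignment of 1 brain array to each blood group, and the erythroid test was given a stricter condition after its value was seen. With blood spots set against brain b and buffy coats against brain a, most genes of white cells and of brain cells took the same direction in both. Neutrophil genes lay higher in blood in both for 22 of 23, T cell genes for 22 of 23, NK and cytotoxic genes for 19 of 20, B cell genes for 18 of 20 and monocyte genes for 18 of 19. Astrocyte genes lay lower in both for 15 of 15, neuronal and synaptic genes for 24 of 26 and oligodendrocyte genes for 17 of 19. Cytosolic ribosomal protein genes had medians of 0.37 and 0.84, with 51 of 84 higher in both, and oxidative phosphorylation genes -2.24 and -1.42, with 78 of 84 lower in both. Erythroid genes had medians of 3.64 for blood spots against brain b and 0.07 for buffy coats against brain a, and 21 of 29 took the same direction. Platelet genes did for 18 of 19, endothelial genes for 10 of 15, skin keratinocyte genes for 5 of 12 (medians 1.98 and -1.28) and olfactory receptor genes for 4 of 11. Over all 22939 genes, 16046 took the same direction. There is 1 brain array in each of these differences, so they have no test.

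Brain b minus brain a, which shares no array with blood spots and buffy coats, had the sign of blood spot minus buffy coat for 85.8% of the called genes. Cytosolic ribosomal protein genes had medians of -1.86 and -2.32 in these differences (same sign for 78 of 84), oxidative phosphorylation genes -1.03 and -2.15 (68 of 81) and proteasome genes -0.88 and -1.73 (26 of 37). Among blood cell lists, monocyte genes (-0.67 and -1.75, same sign for 16 of 19) and neutrophil genes (0.63 and 1.63, 16 of 23) also had medians of the same sign. The other blood cell lists had medians of opposite sign: T cell genes 1.23 and -2.48 (same sign for 15 of 23), NK and cytotoxic genes 1.24 and -2.27 (9 of 20), B cell genes 0.44 and -0.84 (11 of 20), platelet genes 0.94 and -0.91 (7 of 19) and erythroid genes -1.70 and 3.29 (16 of 29). Most T cell, NK and cytotoxic, B cell and platelet genes were not well above background on either brain array. Their brain medians rest largely on background-level values.

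Blood spots and buffy coats differed in most genes, and the erythroid list was higher at camera's preset correlation but not with an estimated correlation (adjusted p = 0.358). Chance is argued against, since of 100 splits of the 18 arrays that part every donor pair 1, the real one, called 12680 genes and the highest other, with 1 pair exchanged, called 10126, and the 2 dimmest blood spots are argued against, since 94.27% of the calls kept their direction without them. Over 17417 genes, the difference correlated with brain b minus brain a at r = 0.8023, so a difference in preparation may account for much of the pattern if brain b was prepared as the blood spots were. Slide and scan day also differed, both between blood spots and buffy coats and between the 2 brain arrays. This trend cannot tell slide or scan day from preparation. For erythroid genes the median residual from that trend, 3.42 over 29 genes, lay at percentile 100 of random lists of the same size, but random lists treat genes as independent, so preparation stays open for them, as does the blood fraction (dried whole blood or buffy coat), an untested biological source. Probe GC content stays open, since its rho with the difference was -0.2829, between the bounds set for and against it. The median difference fell from 1.08 in the fifth of genes with the lowest probe GC to -1.03 in the highest. The share of calls higher in blood spots fell from 74.2% to 33.2%.

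Probes of 1 gene disagreed between blood spots and buffy coats, with probes called in opposite directions in 814 of 4385 genes with several probes tested. The probe nearer the 3' end had the lower blood spot value relative to buffy coat in 63.29% of 3953 genes, so the position of a probe along its gene may contribute. Differences in probe GC content stay open, since their rho with the differences between probes was -0.2156. No biological explanation was tested.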
